A study of Mus musculus with 12 samples.

How the data were processed

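RNA was measured in 12 libraries of C57BL/6 mouse bone marrow cells, 3 in each of 4 groups, per the labels. Total RNA was isolated with a PicoPure kit and libraries were made with a NuGen Ovation kit that does not keep strand, per the labels' protocols. For the wt LSK group the marrow was depleted of lineage-positive cells and sorted for c-Kit and Sca-1. The iMLL-ENL mice received doxycycline until acute leukemia, and their cells came from total marrow or from a sort for high or low B220. The labels give 3 mice per genotype but no mouse for a library. The lowest Xist level was 2516 CPM and no library had more than 2 counts over the Y-linked genes listed, so all libraries came from female mice by these genes.

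The deposited count tables hold raw counts of reads per gene by NCBI gene ID, 24028 genes in each, with wt LSK and iMLL-ENL total in one table and B220 HIGH and B220 LOW in the other. The deposited CPM tables hold a signal that the authors made by dividing the counts by TMM effective library sizes within each table, checked against the counts. The deposited tables also give a width per gene in bases (unit: other), which was not used. The submitters' processing notes name edgeR and the builds GRCm38 and mm10. The aligner and the counting tool are not given in the sources used here. Symbols and coordinates came from a RefSeq annotation of GRCm38, which matched 23968 of the 24028 IDs and left 60 without a symbol.

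Totals per library ran from 10921521 to 22706882 counts. Printed levels are CPM over the library total. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group's libraries, which is 0.0531 CPM for wt LSK, 0.0482 for iMLL-ENL total, 0.0662 for B220 LOW and 0.0591 for B220 HIGH. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval, from the exact binomial interval of the group's share of the counts. Intervals and floors cover counting error only. The library kit does not keep strand, so genes that overlap another annotated gene are uncertain. Among the named genes these are Pax5, Csf1r, Cd34, Trpc6, Bcl2, Itgb2l, Cd72, Gata3, Lck, Rtp4, Zeb1 and Cpa3.

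There were 2 comparisons, each within one count table: iMLL-ENL total against wt LSK and B220 HIGH against B220 LOW. No test of a change in a gene or list crossed the tables. Libraries were compared across them only to check what the replicate numbers mark. The main test was edgeR's quasi-likelihood F test with robust dispersions, TMM factors, the filterByExpr filter with a minimum count of 10, a two-sided p and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 genes tested. The tests, lists, alternatives and rule for named genes were chosen before the data were examined. Of the 22 lists, the sex-linked list served only to check the sex of the mice, and the list of 13 mitochondrially encoded genes had 0 members in the tables. Missing from the tables were also Ly6g, Ighm, Hba-a1, Hbb-bt and Ahsp. This left 20 lists in the first comparison and 18 in the second, where NK cell genes and marrow stroma genes had fewer than 3 genes tested. Some genes stand on more than 1 list, such as Mecom, Flt3, Il7r and Gata2.

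Genes were named by a fixed rule: Kmt2a, Mllt1, Ptprc, Kit and Ly6a; the 6 largest and 6 smallest log2 fold changes among called genes with an average log2 CPM of at least 3 and no overlap between the groups' libraries; up to 2 called members of each list by smallest p; and 16 genes of myeloid, lymphoid and leukemic cells given whichever way they went. List members and genes named outside this rule were chosen after their values were seen. In the second comparison the rule was also applied to the calls of the fit with the replicate block, a choice added after the data were seen. Results for some genes that the rule takes are not reported here.

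The groups share replicate numbers 1 to 3, and the labels do not say what a number marks. For B220 HIGH and B220 LOW, the deviations of same-numbered libraries from their group means correlated across genes at 0.397, 0.198 and 0.307 for numbers 1, 2 and 3. All 3 lie above 0.1, so the numbers were taken to pair these libraries, from this check and not from the labels. The 3 numbers can be matched in only 6 ways, so this check alone cannot exclude chance. The fit with the number as a block stayed an alternative, and its value stands beside the result for each list and each gene named by the rule whose call it changes.

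The tests were tried on counts simulated from the real genes' means, dispersions and library sizes, with 200 genes changed by 2-, 4- or 8-fold. For the first comparison, with 13581 genes tested, 4.55% of 2-fold, 58.5% of 4-fold and 87.7% of 8-fold changes were recovered, and 9 of 107 calls were false, above the nominal share. For the second, with no pair effects and 12243 genes tested, 3.12%, 37.3% and 67.7% were recovered without the block (5 of 76 calls false) and 1.56%, 40.3% and 67.7% with it (9 of 81 false). With simulated pair effects and 12345 genes tested, 0%, 0% and 32.8% were recovered without the block (0 of 21 calls false). With the block 16.9%, 50.7% and 68.8% were recovered (11 of 100 false), so false calls also lay above the nominal share. Each setting was drawn once, and the size of the pair effects was set and not taken from the data, so these shares are rough. The real first comparison had 4221 calls, far more than the 200 genes changed here, so its recovery and false share may differ.

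Alternatives were DESeq2 size factors or library totals in place of TMM, no filter or a filter of at least 10 CPM in 3 libraries, DESeq2's Wald test, limma-voom, the replicate block, a test against a fold change of at least 2, leaving out each library in turn, camera with an estimated correlation, and fry. Other splits of the 6 libraries of a comparison were also fitted. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. The deposited CPM tables were used only for the check of their unit, since the counts carry the same information.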

Results

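RNA was sequenced from 12 libraries of mouse bone marrow cells in 4 groups of 3. The wt LSK group held normal marrow cells depleted of mature lineages and sorted for c-Kit and Sca-1, the compartment of hematopoietic stem cells and multipotent progenitors. The other 3 groups came from leukemic mice with a doxycycline-inducible knock-in of MLL-ENL, a leukemia fusion of the proteins encoded by Kmt2a and Mllt1. One group held leukemic cells of total marrow (iMLL-ENL total), and the other two held cells sorted for high or low B220 (B220 HIGH, B220 LOW), the long isoform of CD45 carried by B cells, plasmacytoid dendritic cells and some other cells. Library totals ran from 18227843 to 19607722 counts in wt LSK, 18001563 to 22706882 in iMLL-ENL total, 13441696 to 16626820 in B220 LOW and 10921521 to 20069503 in B220 HIGH. The labels give 3 mice per genotype and do not say which library came from which mouse, so p-values measure the spread between libraries. Levels are given in CPM over the library total, as mean ± SD with n = 3, and coordinates are on GRCm38.

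The first comparison asked how leukemic marrow cells differed from the normal stem and progenitor compartment. The wt LSK sort itself keeps stem cell genes high and mature lineage genes low in wt LSK, and no other normal cells were compared. The differences below are thus between these cell populations. They do not part leukemia from the sort, from the knock-in genotype or from the doxycycline that the iMLL-ENL mice received. Of 25 genes listed for stem cells and LSK, 23 were lower in the leukemic samples, some of them near 0. Mecom, a stem cell transcription factor (NCBI gene 14013, chromosome 3, 29951296 to 30509759), fell by 10.69 on the log2 scale (SE 0.59, edgeR adjusted p = 1.61e-05), from 157 ± 44.8 to 0.0834 ± 0.0735 CPM. Hlf, another stem cell transcription factor (NCBI gene 217082, chromosome 11, 90336535 to 90390917), fell by 9.14 (SE 0.46, adjusted p = 1.37e-05), from 886 ± 134 to 1.43 ± 0.708 CPM. Of 19 mature neutrophil genes 15 rose and of 18 monocyte and macrophage genes 14, list shifts that did not hold with an estimated correlation between genes (camera adjusted p = 0.437 and 0.284). Elane, which encodes neutrophil elastase (NCBI gene 50701, chromosome 10, 79886312 to 79888216), rose by 6.30 (SE 0.93, adjusted p = 0.00199), from 36.0 ± 34.6 to 2492 ± 2018 CPM. Itgam, which encodes the myeloid integrin CD11b (NCBI gene 16409, chromosome 7, 128062640 to 128118491), rose by 3.32 (SE 0.23, adjusted p = 5.43e-05), from 102 ± 17.2 to 905 ± 156 CPM. In all, edgeR's quasi-likelihood test called 4221 of 13811 genes at an adjusted p under 0.05, of which 2135 were higher and 2086 lower in iMLL-ENL total.

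Kmt2a (NCBI gene 214162, chromosome 9, 44803355 to 44881352), the mouse gene of the first fusion partner, fell by 1.39 (SE 0.26, adjusted p = 0.00446), from 1337 ± 195 to 461 ± 124 CPM. Against a fold change of at least 2 its adjusted p was 0.129. Mllt1 (NCBI gene 64144, chromosome 17, 56892608 to 56935509), which encodes ENL, stood at 42.7 ± 2.23 CPM in wt LSK and 33.3 ± 6.68 CPM in iMLL-ENL total (log2 change -0.20, SE 0.23, adjusted p = 0.542). The labels do not give the knock-in construct or the species of its ENL part, so whether these counts hold fusion reads is not known. If they do, gene counts do not separate the fusion transcript from those of the normal alleles. Ptprc, which encodes CD45 and its B220 isoform, had 595 ± 52.6 and 680 ± 109 CPM (log2 change 0.35, SE 0.19, adjusted p = 0.202). Kit (chromosome 5, 75574987 to 75656722) fell by 3.09 (SE 0.24, adjusted p = 8.59e-05) and Ly6a, which encodes Sca-1 (chromosome 15, 74994877 to 74998031), fell by 4.71 (SE 0.41, adjusted p = 0.000125). Both products defined the LSK sort, which selects for high levels in wt LSK.

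The plot of list members shows the gene lists fixed for this comparison. Of 25 stem cell and LSK genes, 23 fell and 2 did not pass, with 23 lower when adjusted over the list alone (camera adjusted p = 3.94e-33). This was the only list whose shift held when camera estimated the correlation between genes (adjusted p = 0.00479). Besides Mecom and Hlf, Cd34 fell by 3.13 (SE 0.52, adjusted p = 0.00303). Of 13 erythroid genes, 11 fell, also 11 when adjusted over the list alone, and 2 did not pass (camera adjusted p = 3.14e-08, adjusted p = 0.0828 with an estimated correlation). Car2, a carbonic anhydrase gene (chromosome 3, 14886269 to 14900770), fell by 10.45 (SE 0.71, adjusted p = 6.33e-05), from 570 ± 35.6 to 0.369 ± 0.339 CPM. Of 13 megakaryocyte and platelet genes, 9 fell, 1 (Gp1bb) rose and 3 did not pass, with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 9.50e-08, adjusted p = 0.0828 with an estimated correlation). Rab27b, a vesicle traffic gene of platelets, had 1190 counts in wt LSK and 2 in iMLL-ENL total, a ratio of 657 with a counting interval of 181 to 5427 (adjusted p = 0.000111).

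**Figure D1:**
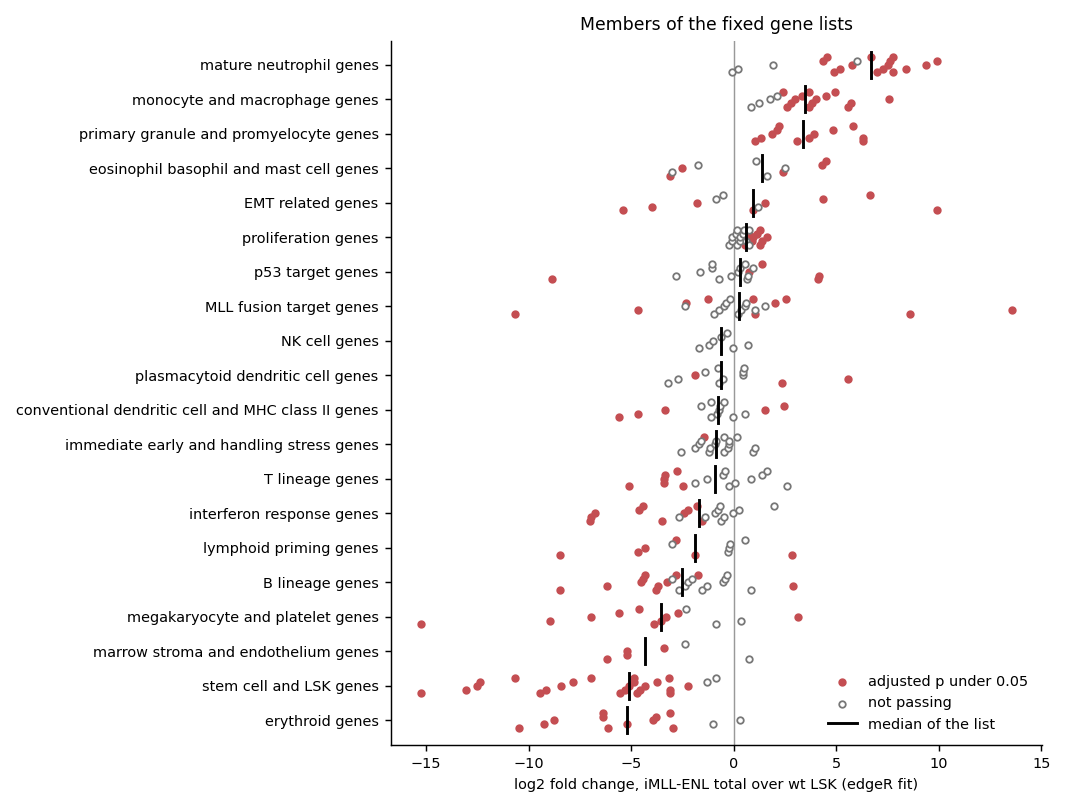
Each point is 1 gene of a fixed list, placed by its log2 fold change of iMLL-ENL total over wt LSK (n = 3 libraries each); filled points have an adjusted p under 0.05, black bars are list medians, and fitted values of genes with 0 counts in a group are no bounds. The median was -5.08 for stem cell and LSK genes, -5.20 for erythroid genes, 3.38 for primary granule genes and 6.70 for mature neutrophil genes.

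Myeloid lists moved the other way. All 12 primary granule and promyelocyte genes rose, over all genes and when adjusted over the list alone (camera adjusted p = 6.67e-08, adjusted p = 0.181 with an estimated correlation). Among them, Ctsg, the cathepsin G gene (chromosome 14, 56099885 to 56102574), rose by 3.91 (SE 0.39, adjusted p = 0.000251). Gfi1, a transcription factor of granulocytes, rose by 3.09 (SE 0.37, adjusted p = 0.000619). Mpo, the myeloperoxidase gene (chromosome 11, 87793784 to 87804412), was already high in wt LSK at 1438 ± 324 CPM and rose to 6037 ± 3302 CPM (adjusted p = 0.00305). Of 19 mature neutrophil genes, 15 rose and 4 did not pass, with 17 higher when adjusted over the list alone (camera adjusted p = 2.91e-07, adjusted p = 0.437 with an estimated correlation). Chil3, which encodes a chitinase-like protein of myeloid cells (chromosome 3, 106147554 to 106167564), rose by 9.36 (SE 1.01, adjusted p = 0.000486), from 5.86 ± 4.67 to 3405 ± 1674 CPM. Itgb2l rose by 7.78 (SE 0.99, adjusted p = 0.000893), and its span overlaps Igsf5, so its counts are uncertain. Of 18 monocyte and macrophage genes, 14 rose and 4 did not pass, with 15 higher when adjusted over the list alone (camera adjusted p = 3.72e-10, adjusted p = 0.284 with an estimated correlation). Adgre1, which encodes F4/80 (chromosome 17, 57358581 to 57483529), rose from 1.95 ± 0.785 to 92.1 ± 28.9 CPM (adjusted p = 6.33e-05), and Csf1r, the receptor gene for the macrophage growth factor CSF1, from 30.1 ± 16.7 to 186 ± 84.8 CPM (adjusted p = 0.0025). Of 23 proliferation genes, 10 rose and 13 did not pass, with 11 higher when adjusted over the list alone (camera adjusted p = 0.00634, adjusted p = 0.422 with an estimated correlation). Their changes were small, with a median of 0.61: Aurkb rose by 1.13 (SE 0.18, adjusted p = 0.00244, but 0.376 against a fold change of at least 2) and Rrm2 by 1.61 (SE 0.27, adjusted p = 0.00265).

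Of 20 interferon response genes, 10 fell and 10 did not pass, with 14 lower and 1 higher when adjusted over the list alone (camera adjusted p = 6.67e-08, adjusted p = 0.0828 with an estimated correlation). Oasl2, an antiviral gene (chromosome 5, 114896926 to 114912245), fell by 6.94 (SE 0.33, adjusted p = 1.37e-05), from 161 ± 11 to 1.17 ± 0.487 CPM. Rtp4 fell by 7.01 (SE 0.60, adjusted p = 0.000115), with a span that overlaps Masp1. Of 22 B lineage genes, 10 fell, 1 (Bst1) rose and 11 did not pass, with 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00634, adjusted p = 0.672 with an estimated correlation). Dntt, the lymphoid polymerase TdT gene (chromosome 19, 41029275 to 41059525), fell from 542 ± 443 to 1.43 ± 2.32 CPM (adjusted p = 0.00755). Foxo1 fell by 1.74 (SE 0.25, adjusted p = 0.0013) and Cd72, whose span overlaps Tesk1, by 4.52 (SE 0.46, adjusted p = 0.000268). Ebf1, an early B cell factor, fell by 3.24 (SE 0.87, adjusted p = 0.0243), while Pax5, Cd79a and Rag1 did not pass (adjusted p = 0.195, 0.365 and 0.0944). One normal library stood apart here, a point singled out after the values were seen: wt LSK replicate 2 had 1053 CPM of Dntt, 61.9 of Ebf1 and 14.2 of Cd79a, against 311 and 262 of Dntt in the other two. Without it the B lineage median was -1.34 (camera adjusted p = 0.0597) and the log2 change of Ebf1 -2.18 (adjusted p = 0.0868). Ebf1 also lost its call without iMLL-ENL total replicate 3 (adjusted p = 0.0699) and against a fold change of at least 2 (0.0624), and Rag1 gained one without iMLL-ENL total replicate 2 (log2 change -5.19, adjusted p = 0.0284) and with the replicate number as a block (-3.31, 0.00372).

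Of 22 genes listed as targets of MLL fusions, 6 rose, 4 fell and 12 did not pass, with 6 higher and 7 lower when adjusted over the list alone, and the list did not shift (median 0.28, mean 0.41, camera direction down, adjusted p = 0.298). Singled out after their values were seen, Eya1 had 280, 0.889 and 43.6 CPM in iMLL-ENL total replicates 1, 2 and 3 and 130 to 140 CPM in wt LSK. Six4 had 148, 8.50 and 1.76 CPM in iMLL-ENL total and at most 0.269 CPM in wt LSK. Hoxa9 (chromosome 6, 52223097 to 52227370) had 119, 166 and 13 CPM in the leukemic libraries and 85.1 ± 15.3 CPM in wt LSK, with no call (log2 change 0.36, SE 0.70, adjusted p = 0.734). Without iMLL-ENL total replicate 3 its change was 0.83 (adjusted p = 0.032) and that of Hoxa10 2.05 (adjusted p = 0.00181, against 0.231 with all libraries). Without iMLL-ENL total replicate 2 the change of Hoxa9 was -0.23, while limma-voom gave -0.28 and the fit with the replicate block -0.16. Meis1, a homeobox partner of the Hox proteins (chromosome 11, 18880428 to 19019651), fell by 1.25 (SE 0.37, adjusted p = 0.0353), from 437 ± 39.4 to 168 ± 101 CPM. Its call was lost without wt LSK replicate 1, 2 or 3 (adjusted p = 0.104, 0.0609 and 0.0936), without iMLL-ENL total replicate 2 or 3 (0.117 and 0.0539), and against a fold change of at least 2 (0.412). Bcl2, an anti-apoptotic gene (chromosome 1, 106538176 to 106714290), fell by 2.31 (SE 0.19, adjusted p = 9.1e-05), and Flt3, a cytokine receptor gene, fell by 4.67 (SE 0.63, adjusted p = 0.00124).

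The rule for named genes took the 6 largest rises. Among them was Olfm4, which encodes a neutrophil granule protein (chromosome 14, 80000302 to 80023141), with 1 count in wt LSK and 156 ± 128 CPM in iMLL-ENL total, a ratio of 8437 with a counting interval of 1514 to 333271 (adjusted p = 0.000632). Colec12, a scavenger receptor gene, had 0 counts in wt LSK and 27.7 ± 6.98 CPM, at least 521-fold higher (adjusted p = 0.000111). The RNA gene 4933440M02Rik had 0 counts and 25.5 ± 16.8 CPM, at least 479.7-fold higher (adjusted p = 0.000607). BC018473 had 3 counts and 215 ± 83.0 CPM, a ratio of 4069 with a counting interval of 1392 to 19733 (adjusted p = 1.43e-05). Tshr, the thyrotropin receptor gene, had 2 counts and 79.0 ± 65.1 CPM, a ratio of 2102 with an interval of 582 to 17364 (adjusted p = 0.000299). Among the 6 largest falls were Myct1, Pgr, Trpc6, Mycn and Fzd6, each with 0 counts in iMLL-ENL total and at least 923-fold (Fzd6) to 2447-fold (Myct1) lower. Trpc6 overlaps another annotated gene, Gm32014.

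Of 6 marrow stroma and endothelium genes, 4 fell and 2 did not pass, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.309 with an estimated correlation). Bgn fell from 18.5 ± 7.27 to 0.233 ± 0.330 CPM (adjusted p = 0.00203) and Kdr from 5.47 ± 2.76 to 0.126 ± 0.132 CPM (adjusted p = 0.00278). That list shift was lost without wt LSK replicate 1 or 2 (adjusted p = 0.11 and 0.133), without iMLL-ENL total replicate 1 or 3 (0.243 and 0.0914) and with no filter on low counts (0.188). In the 9 remaining lists camera found no shift. Adjusted over the list alone their counts were as given over all genes, except that 3 genes of eosinophils, basophils and mast cells and 4 of plasmacytoid dendritic cells were lower, and where another count is given. Lymphoid priming genes had 5 lower and 1 higher of 11 (median -1.87, adjusted p = 0.0731), among them Satb1, which fell by 4.34 (SE 0.57, adjusted p = 0.00108). That list passed without wt LSK replicate 1 or 3 (adjusted p = 0.0372 and 0.0068), without iMLL-ENL total replicate 2 (0.0172), with no filter (0.0377) and with the replicate block (0.0289), and its median was -1.06 without wt LSK replicate 2 (0.133). T lineage genes had 6 lower of 16 (adjusted p = 0.0849), among them Gata3, which fell by 5.09 (SE 0.71, adjusted p = 0.00122), and Lck, and passed without wt LSK replicate 3 (0.0263) or iMLL-ENL total replicate 2 (0.0146). Immediate early and handling stress genes had 1 lower of 17, Jun, and 0 when adjusted over the list alone (adjusted p = 0.219), and passed without wt LSK replicate 3 (0.00365) or iMLL-ENL total replicate 3 (0.0446). Jun fell by 1.45 (SE 0.39, adjusted p = 0.0221), with no call without wt LSK replicate 1 or 2 (0.0815 and 0.0674), without iMLL-ENL total replicate 1 or 2 (0.0598 and 0.0809), with the replicate block (0.117), or against a fold change of at least 2 (0.218).

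Conventional dendritic cell and MHC class II genes had 2 higher, among them Id2 (log2 change 2.46, SE 0.50, adjusted p = 0.00671), and 3 lower of 14, with 2 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.252). Genes of eosinophils, basophils and mast cells had 3 higher and 2 lower of 10 (camera adjusted p = 0.426), with Hdc, the histamine synthesis gene, rising from 4.35 ± 0.793 to 77.9 ± 36.4 CPM (adjusted p = 0.000268) and Gata2 falling from 152 ± 5.02 to 16.2 ± 13.7 CPM (adjusted p = 0.00904). Targets of p53 had 4 higher and 1 lower of 17, with a median of 0.32, a mean of -0.15 and a camera direction of up (adjusted p = 0.426). Among them, Fas rose by 4.11 (SE 0.48, adjusted p = 0.000527) and Pmaip1, which encodes Noxa, by 4.16 (SE 0.55, adjusted p = 0.00106). EMT related genes had 5 higher and 3 lower of 11, with a median of 0.92, a mean of 1.09 and a camera direction of down (adjusted p = 0.426). Zeb1, a transcription factor (chromosome 18, 5591327 to 5775468), fell by 5.42 (SE 0.22, adjusted p = 8.55e-06), and Tcf7l2 fell by 3.99 (SE 0.46, adjusted p = 0.00048). Plasmacytoid dendritic cell genes had 2 higher and 1 lower of 12 (camera adjusted p = 0.838), and NK cell genes none of 7 (camera adjusted p = 0.752). Among the former, Ly6c2 rose by 5.59 (SE 0.96, adjusted p = 0.00396), and Siglech stood at 74.7 CPM in wt LSK replicate 2 and at most 5.41 CPM in the other wt LSK libraries. Tlr9 had an adjusted p of 0.04 and lost its call in 9 of 14 alternative settings, among them without wt LSK replicate 1 or 3 (0.15 and 0.125), without iMLL-ENL total replicate 3 (0.14) and with the replicate block (0.149).

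Of the called genes named by the rule, all but Tlr9 had every leukemic library on the same side of every wt LSK library. The rule itself required this of the genes with the largest and smallest changes, so for them it is no support of its own. The other genes counted here had to be called, which favors such a separation. The count of 4221 changed genes was 2658 without wt LSK replicate 1, 2636 without wt LSK replicate 3, and 2047 against a fold change of at least 2. Library totals in place of TMM moved the median log2 change of all genes from 0.05 to -0.10, and other changes are relative to that shift. The balance of calls depended on the scaling: 1689 genes were higher and 2447 lower with library totals, and 1979 and 2212 with DESeq2 size factors.

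Levels were set side by side for all 4 groups without a test, since the 2 count tables hold different groups. Mecom had at most 0.139 CPM in any iMLL-ENL total library and 0.0200 ± 0.0347 CPM in B220 LOW and 0.507 ± 0.444 CPM in B220 HIGH. Kit had 1161 ± 164 CPM in wt LSK, 123 ± 32.0 in iMLL-ENL total, 41.6 ± 28.0 in B220 LOW and 29.8 ± 19.5 in B220 HIGH. Elane had 2492 ± 2018 CPM in iMLL-ENL total, 1399 ± 960 in B220 LOW and 154 ± 173 in B220 HIGH. Mpo had 6037 ± 3302 CPM in iMLL-ENL total, but 754 ± 880 in B220 LOW and 152 ± 201 in B220 HIGH. Both sorted means of Mpo lay below the 1438 ± 324 CPM of wt LSK. In each replicate number Mpo was higher in iMLL-ENL total than in either sorted fraction. Hoxa9 ranged from 13 to 237 CPM over the 9 leukemic libraries.

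**Figure D2:**
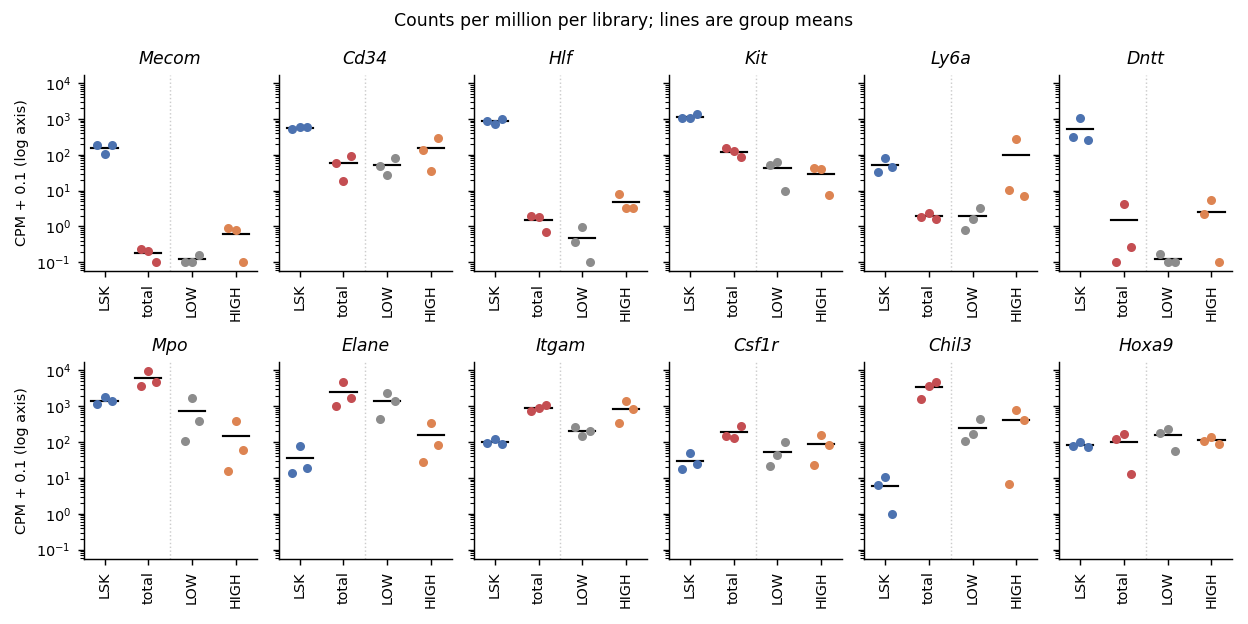
Levels of 12 genes in every library of the 4 groups, in CPM plus 0.1 on a log axis; short lines are group means (n = 3), and the dotted line divides the 2 count tables. Mecom, Hlf and Kit were above every leukemic library in each of the 3 wt LSK libraries.

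The second comparison asked how leukemic cells with high B220 differed from those with low B220. No gene passed the main test. The gene nearest to it was Serpinb2, a protease inhibitor gene (NCBI gene 18788, chromosome 1, 107500892 to 107525600), at 0.257 ± 0.302 CPM in B220 LOW and 58.6 ± 12.6 CPM in B220 HIGH (log2 change 7.84, SE 0.85, edgeR adjusted p = 0.0649). It passed with no filter on low counts (0.00107), with a stricter filter of at least 10 CPM in 3 libraries (0.0356), with DESeq2 (9.12e-30) and without replicate 1 of B220 HIGH or of B220 LOW (0.0234 and 0.0274). Libraries with the same replicate number varied together, and with the number as a block edgeR called 79 genes, 73 higher and 6 lower in B220 HIGH. Serpinb2 passed there too (log2 change 8.04, SE 0.72, adjusted p = 0.00235), as did 4 granule genes that were lower in B220 HIGH. Elane fell by 3.56 with the block (SE 0.28, adjusted p = 0.00235, against 0.58 without it), from 1399 ± 960 to 154 ± 173 CPM. Ptprc itself, whose product carries B220, had 427 ± 185 CPM in B220 LOW and 562 ± 33.7 CPM in B220 HIGH (log2 change 0.47, SE 0.31, adjusted p = 0.852), higher in 2 of 3 pairs.

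Without the block, edgeR called 0 of 12564 genes, with 880 at an unadjusted p under 0.05. By other tools, limma-voom called 0 genes and DESeq2 302. With no filter on low counts edgeR called 22 genes, and with a filter of at least 10 CPM in 3 libraries it called 4. The block also changed which genes could be named, so the rule for named genes was applied to its calls after the data were seen. Kmt2a (350 ± 148 and 387 ± 139 CPM), Mllt1 (22.3 ± 4.48 and 22.4 ± 7.42 CPM), Kit, Hoxa9, Hoxa10, Meis1, Csf1r, Cd34 and Flt3 passed neither test. Itgam had 207 ± 53.7 CPM in B220 LOW and 856 ± 521 CPM in B220 HIGH (log2 change 2.14, adjusted p = 0.309, and 0.362 with the block), and passed with DESeq2 (0.00206) and without B220 HIGH replicate 1 (0.0234). Ebf1, Pax5, Cd79a, Rag1, Dntt and Mecom did not reach the filter's minimum in enough libraries to enter the test. Ebf1 had 0, 14.1 and 2.78 CPM in B220 HIGH replicates 1, 2 and 3, and Dntt 2.11, 5.23 and 0 CPM.

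Among the 6 lower genes with the block, Mpo fell by 2.53 (SE 0.18, adjusted p = 0.000701, against 0.841 without it), Ctsg by 1.91 (SE 0.28, adjusted p = 0.0442, against 0.132) and Asns, the asparagine synthetase gene (chromosome 6, 7675165 to 7693209), by 1.44 (SE 0.24, adjusted p = 0.0447, against 0.412). Among the 73 higher, Cpa3, a mast cell protease gene (NCBI gene 12873, chromosome 3, 20215616 to 20242209), had 4.77 ± 5.94 CPM in B220 LOW and 583 ± 460 CPM in B220 HIGH (log2 change 7.43 with the block, SE 0.64, adjusted p = 0.0178, against 0.412). Cxcl3, a neutrophil chemokine gene (chromosome 5, 90786101 to 90788093), rose by 7.29 with the block (SE 0.77, adjusted p = 0.00493, against 0.132). Bcl11a, a transcription factor gene (chromosome 11, 24076564 to 24173558), rose by 7.63 with the block (SE 0.81, adjusted p = 0.00493, against 0.452) and stood at 4.67, 144 and 1.26 CPM in B220 HIGH replicates 1, 2 and 3. The transporter genes Slc9a4 (log2 change 7.41, adjusted p = 0.0281) and Slc45a3 (6.70, 0.0347) were the others with the largest rises under the block. Ly6a passed neither test (adjusted p = 0.48 without the block), with 10.5, 285 and 6.88 CPM in B220 HIGH and at most 3.25 CPM in B220 LOW.

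**Figure D3:**
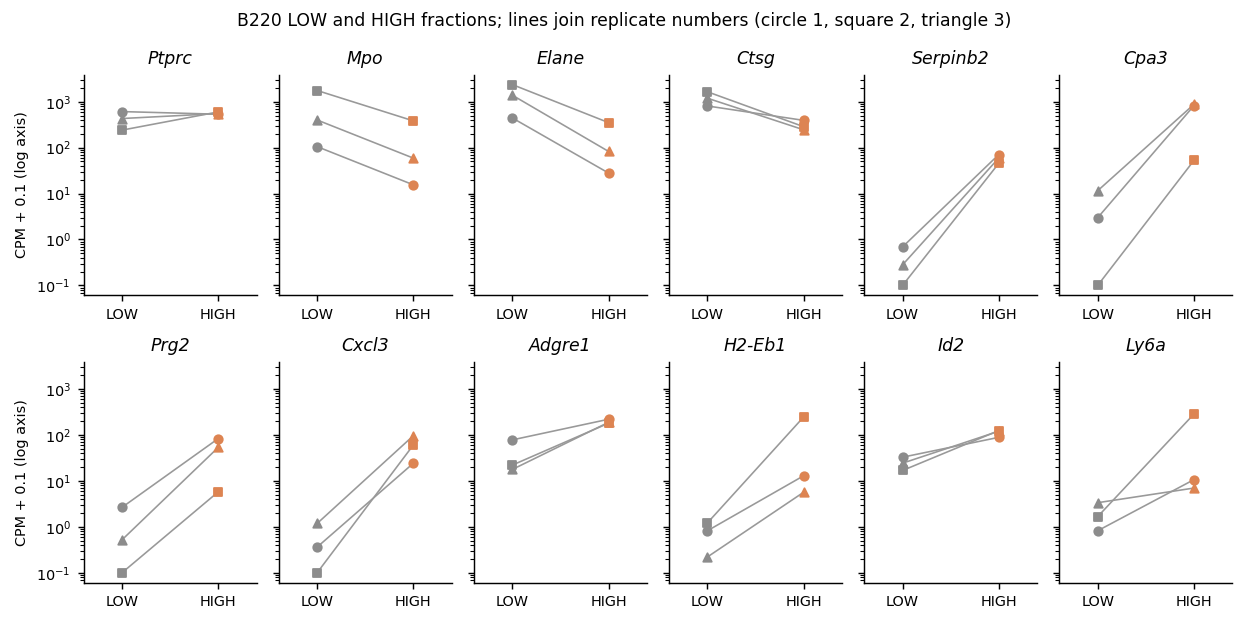
Levels of 12 genes in B220 LOW and B220 HIGH, in CPM plus 0.1 on a log axis, with a line joining the libraries of each replicate number (3 pairs). Mpo, Elane and Ctsg were lower in B220 HIGH in all 3 pairs and Serpinb2, Cpa3, Prg2 and Cxcl3 higher in all 3, while Ptprc was higher in 2.

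Camera found a shift in 15 of 18 lists, 13 up and 2 down, and in 13 with the block. None held with an estimated correlation (lowest adjusted p = 0.13 without and 0.189 with the block). No member of any list passed over all genes without the block, so the counts here are those adjusted over the list alone, and members that passed only there are named after their values were seen. With the block these counts were 2 of 10 higher for conventional dendritic cell and MHC class II genes, 7 of 17 higher and 1 lower for monocyte and macrophage genes, 4 higher each for stem cell and LSK, megakaryocyte and platelet, and EMT related genes, 3 higher for lymphoid priming genes, 2 higher each for p53 and MLL fusion targets, 3 of 23 lower for proliferation genes and 1 of 12 lower for plasmacytoid dendritic cell genes. Apart from the primary granule and the immediate early lists, given below, the other lists had the same counts with the block. Genes of eosinophils, basophils and mast cells had 5 of 7 higher (median 4.8, camera adjusted p = 6.77e-09, adjusted p = 0.13 with an estimated correlation). They were Cpa3, Epx, Gata2, Hdc and Prg2, and with the block Cpa3, Epx and Prg2 also passed over all genes. Prg2, which encodes the eosinophil major basic protein (chromosome 2, 84980461 to 84983632), rose by 6.17 with the block (SE 0.69, adjusted p = 0.00622, against 0.377). Conventional dendritic cell and MHC class II genes had 6 of 10 higher (median 2.71, camera adjusted p = 1.14e-08, adjusted p = 0.13 with an estimated correlation). Id2 (log2 change 2.26, SE 0.33, adjusted p = 0.0228) and H2-Eb1 (6.05, SE 0.77, adjusted p = 0.0182) passed with the block. B220 HIGH replicate 2 stood apart in these genes, chosen after their values were seen, with 1783 CPM of Cd74 and 925 of H2-Aa against 117 and 49.5 in replicate 1 and 123 and 42.9 in replicate 3. No B220 LOW library had more than 15.5 CPM of Cd74.

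Monocyte and macrophage genes had 3 of 17 higher, Cd68, Adgre1 and Itgam (median 1.09, camera adjusted p = 5.83e-08, adjusted p = 0.154 with an estimated correlation). With the block Adgre1 rose by 2.70 (SE 0.39, adjusted p = 0.0313, against 0.236), from 39.2 ± 33.7 to 196 ± 20.8 CPM, and Mpeg1, a pore-forming protein gene of macrophages, by 2.25 (SE 0.28, adjusted p = 0.0153). Primary granule and promyelocyte genes had 1 of 12 lower, Ctsg (median -0.71, camera adjusted p = 0.00151, adjusted p = 0.23 with an estimated correlation). With the block 4 of them passed over all genes, and 5 were lower and 1 higher adjusted over the list alone. Mature neutrophil genes had 2 of 18 higher, Mmp8 and Ifitm6 (median 1.79, camera adjusted p = 0.00233, adjusted p = 0.413 with an estimated correlation). That shift was lost with the block (median 0.46, adjusted p = 0.104) and without B220 HIGH replicate 2 (median 0.34, adjusted p = 0.78, camera direction down), a library with 7656 CPM of S100a9 against 31.5 and 1674 in the other two. With the block the median ran from -0.858 to 2.04 when a pair was left out. The list then passed only without the replicate 1 pair (camera adjusted p = 2.47e-09).

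B lineage genes had 3 of 12 higher, Bst1, Cd22 and Il7r (median 1.23, camera adjusted p = 0.000449, adjusted p = 0.154 with an estimated correlation). Il7r encodes the interleukin 7 receptor and Bst1 a cell surface enzyme that myeloid cells also carry, while Cd79b, a part of the B cell receptor, had 8.28 ± 3.53 CPM in B220 LOW and 8.25 ± 1.41 CPM in B220 HIGH. Without B220 HIGH replicate 2 the list had a median of 0.23 and an adjusted p of 0.0835. With the block its median was 0.40 (adjusted p = 0.00229), and -0.00744 without the replicate 2 pair (0.165). Lymphoid priming genes had 1 of 9 higher, Il7r (median 1.76, camera adjusted p = 6.62e-06, adjusted p = 0.13 with an estimated correlation). T lineage genes had none of 11 (median 0.54, camera adjusted p = 0.0347, adjusted p = 0.154 with an estimated correlation), a shift lost with the block (0.148), without B220 HIGH replicate 1 or 2 (0.168 and 0.285) and without B220 LOW replicate 3 (0.201). Plasmacytoid dendritic cell genes had none of 12 and no shift (median 0.996, camera adjusted p = 0.06), with Siglech at 66.7 CPM in B220 HIGH replicate 2 and at most 2.02 CPM in the other sorted libraries. That list passed without B220 HIGH replicate 1 (0.000368) or 3 (0.0228), without B220 LOW replicate 2 (0.0114) or 3 (0.0459), with library totals (0.0455) and with no filter (0.0197), while without B220 HIGH replicate 2 its median fell to 0.27 (0.78).

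Stem cell and LSK genes had none of 15 over the list alone, with a median of 1.61 (camera adjusted p = 5.7e-05, adjusted p = 0.13 with an estimated correlation). With the block Ifitm1 rose by 1.94 (SE 0.24, adjusted p = 0.0107). Megakaryocyte and platelet genes had none of 10 (median 2.02, camera adjusted p = 0.000288, adjusted p = 0.13 with an estimated correlation). EMT related genes had 2 of 12 higher, Cdh1 and Fn1 (median 1.07, camera adjusted p = 4.08e-05, adjusted p = 0.13 with an estimated correlation), and Cdh1, the E-cadherin gene (chromosome 8, 106603350 to 106670247), rose by 4.43 with the block (SE 0.67, adjusted p = 0.0396). Immediate early and handling stress genes had 1 of 16 higher, Klf6, and 5 with the block (median 0.90, camera adjusted p = 5.7e-05, adjusted p = 0.243 with an estimated correlation), and Egr1 rose by 2.72 with the block (SE 0.33, adjusted p = 0.0108, against 0.693). Targets of p53 had none of 16 (median 0.58, camera adjusted p = 0.00163, adjusted p = 0.13 with an estimated correlation). Proliferation genes had none of 23 and a small downward shift (median -0.31, camera adjusted p = 0.000984, adjusted p = 0.198 with an estimated correlation). Interferon response genes had none of 17 (median 0.42, camera adjusted p = 0.0266, adjusted p = 0.255 with an estimated correlation), a shift lost without B220 LOW replicate 2 (0.0555), without B220 HIGH replicate 3 (0.0679) and with the stricter filter (0.25). MLL fusion targets had 1 of 21 higher, Bcl2, and no shift (camera adjusted p = 0.163), which passed without B220 HIGH replicate 3 (0.0348). The 3 erythroid genes tested had no shift (median 0.15, camera direction down, adjusted p = 0.978).

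Leaving out a library changed the calls: 96 genes passed without B220 HIGH replicate 1 and 3 without B220 LOW replicate 1, both without the block. Among genes named by the rule, Cxcl3 (adjusted p = 0.0238) and Id2 (0.0261) also passed without B220 HIGH replicate 1, and Adgre1 (0.0193) without B220 LOW replicate 1. Without the block, Ctsg (0.0217) and Id2 (0.0201) passed with no filter, and DESeq2 called Adgre1, Cdh1, Cpa3, Ctsg, Cxcl3, Id2, Mpeg1, Prg2, Slc45a3 and Slc9a4. With the block, 292, 197 and 10 genes passed without both libraries of replicates 1, 2 and 3. Without the replicate 3 pair, Mpo (adjusted p = 0.0607), Elane (0.0828), Serpinb2 (0.125), Cxcl3, Ifitm1 and Mpeg1 (0.213 each), Prg2 (0.219), Cdh1 (0.337), Adgre1 (0.366), Slc9a4 (0.399), H2-Eb1 (0.418), Id2 (0.419), Asns (0.441), Ctsg (0.465) and Slc45a3 (0.473) lost their calls. Their log2 changes kept their direction with the 2 pairs left, from a larger one for Slc9a4 (10.34 against 7.41 with all pairs) and Cxcl3 (8.12 against 7.29), through Elane (-3.30 against -3.56), to the largest relative loss, in Asns (-1.07 against -1.44). Adgre1 (0.103), H2-Eb1 (0.13) and Bcl11a (0.411) lost theirs without the replicate 2 pair, with log2 changes of 2.49, 4.76 and 6.02, and Cpa3 and Egr1 kept theirs without any pair. Cpa3 lost its call with the block and no filter (0.165) or the stricter filter (0.0739), as did Ctsg (0.0641 and 0.0653), while Cdh1 lost it with the stricter filter (0.0588) and Asns with DESeq2 size factors (0.0588). Against a fold change of at least 2 with the block, Slc45a3 (0.0623), Cdh1 (0.084), Ifitm1 and Mpeg1 (0.0853 each), Adgre1 (0.117), Id2 (0.128), Ctsg (0.24) and Asns (0.79) had no call. Without B220 HIGH replicate 2 and no block, list medians fell to 0.85 for conventional dendritic cell and MHC class II genes, 0.78 for lymphoid priming genes and 0.54 for immediate early and handling stress genes, and to -1.56 for primary granule genes. Each gene named by the rule and called with the block moved the same way in 3 of 3 pairs. The choice of these genes from the blocked calls largely fixed this, so it is no support of its own.

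Leukemic libraries of the same number also shared genes across the 2 count tables, as the plot of these genes by replicate number shows. Eya1 had 210, 0.372 and 86 CPM in B220 LOW replicates 1, 2 and 3 and 149, 4.88 and 52.9 CPM in B220 HIGH, highest in replicate 1 as in iMLL-ENL total.

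**Figure D4:**
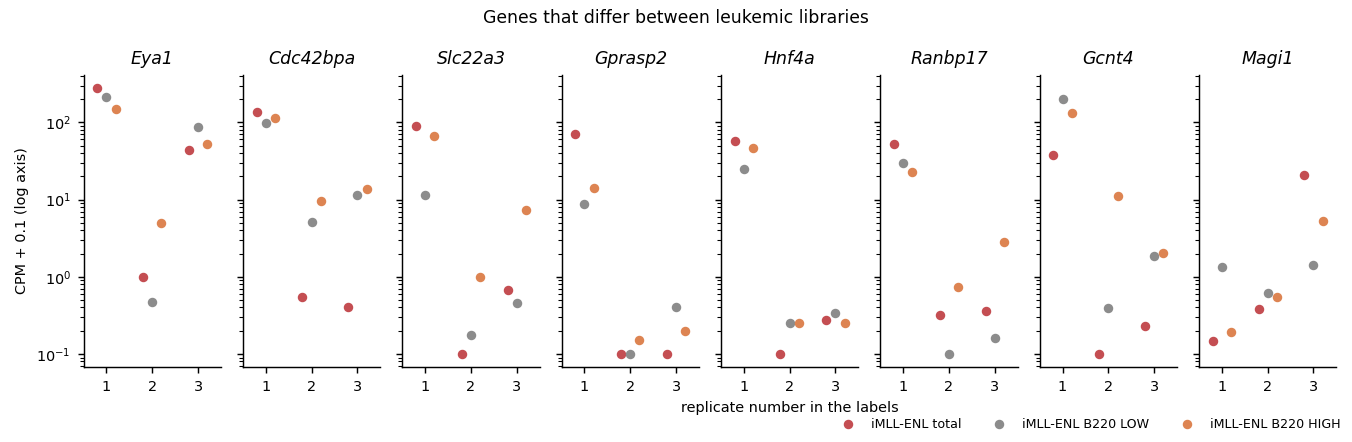
Levels of Eya1 and 7 genes that were on in only 1 iMLL-ENL total library, in CPM plus 0.1 on a log axis, by replicate number for iMLL-ENL total, B220 LOW and B220 HIGH (1 point per library). The 7 genes were chosen after their values in iMLL-ENL total were seen, and each was highest in the sorted libraries of the same number.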

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

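The settings that combine the block with another choice, and those that leave out both libraries of a number, were chosen after the data were seen, while the other alternatives were planned. Against a fold change of at least 2, the first comparison had 2047 changed genes, 868 higher and 1179 lower, because the test asks for a larger change. Over the 6 fits that left out 1 library it had 2636 to 4528, with 1181 to 2253 higher and 1383 to 2275 lower, and the other settings gave 2988 (stricter filter) to 5205 (DESeq2). The shifted lists were 10 in the main setting, 8 to 13 without 1 library, and 1 with an estimated correlation. In that comparison the replicate numbers did not pair the libraries: deviations correlated at 0.0164, 0.160 and -0.0358 for numbers 1, 2 and 3, and of the wt LSK libraries replicate 2 alone correlated best with its own number. With the number as a block 4048 genes changed, 3777 of them also called without it, and 11 lists shifted, 0 of them with an estimated correlation.

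B220 HIGH against B220 LOW went from 0 changed genes to 22 with no filter (21 higher, 1 lower), 4 with the stricter filter (4 higher), 302 with DESeq2 (275 higher, 27 lower) and 79 with the replicate block (73 higher, 6 lower), and stayed at 0 with DESeq2 size factors, library totals, limma-voom and the fold change of at least 2. Without 1 library the count was 0 to 96, with 0 to 96 higher and 0 to 0 lower. With the block and no filter it was 198 (181 higher, 17 lower), with the stricter filter 99 (87 higher, 12 lower), with DESeq2 763 (637 higher, 126 lower), with limma-voom 302 (267 higher, 35 lower), and against a fold change of at least 2 it was 39 (36 higher, 3 lower). Without both libraries of replicates 1, 2 and 3 the block gave 292, 197 and 10 genes, with 270, 166 and 10 higher and 22, 31 and 0 lower. The shifted lists were 15, 12 to 16 without 1 library, 0 with an estimated correlation and 2 with fry. With the block they were 13, 11 to 15 without a pair, 0 with an estimated correlation and 1 with fry. The mature neutrophil list reversed in its test without B220 HIGH replicate 2 (median 0.34, adjusted p = 0.78, with medians of 0.34 to 2.32 without 1 library). Besides the calls given in the results, the block changed no other call of a list or of a gene named by the fixed rule in this comparison. For all these changes the cause was not tested.

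Over the settings other than leaving out a library, named genes of the first comparison kept their direction and call in 484 cases, lost the call in 14, gained it in 1 and changed sign without a call in 2. Without 1 library these counts were 361, 18, 3 and 2. Levels moved by no more than their SD in 84 of 84 cases when CPM were taken over TMM effective library sizes, of which Pax5 and Rag1 in B220 LOW, at 0 in each library, could not move. Depth limits genes near the floors of 0.0482 to 0.0662 CPM, where a difference was not detectable.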

Other observations

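The tests of the replicate numbers, of other cells behind a high B220 signal and of normal marrow were chosen after the results were seen, while the splits of the libraries were planned.

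Among the 73 genes higher in B220 HIGH with the replicate block were 7 of the 15 Ccl and Cxcl chemokine genes tested, a group noticed after its values were seen. Ccl2, a monocyte attractant gene (chromosome 11, 82035577 to 82037452), rose by 4.14 on the log2 scale with the block (SE 0.26, edgeR adjusted p = 0.000392, against 0.412 without it), with 17, 29.4 and 87.3 CPM in B220 LOW replicates 1, 2 and 3 and 188, 495 and 2306 CPM in B220 HIGH. Ccl6 (chromosome 11, 83587886 to 83593087) rose by 3.74 (SE 0.21, adjusted p = 0.000392, against 0.181). The others were Cxcl3, Ccl7, Cxcl2, Ccl3 and Ccl4, and the annotated spans of Ccl3 and Ccl4 overlap, so their counts are uncertain, and none of the 7 passed without the block. The list of immediate early and handling stress genes shifted up as well (14 of 16 positive with the block, median 0.88, camera adjusted p = 2.68e-06, 0.346 with an estimated correlation). A response to sorting or handling thus stays open beside a difference between the cells, and neither was tested for the chemokine genes. In iMLL-ENL total replicates 1, 2 and 3 Ccl2 had 11.2, 34.5 and 36.2 CPM. This was below both sorted fractions in replicates 1 and 3 and between them in replicate 2. A gate for iMLL-ENL total is not given in the labels, so these levels do not decide.

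Leukemic libraries with the same number may come from the same mouse. Of 7 genes at 20 CPM or more in 1 iMLL-ENL total library and at most 1 CPM in the other two, the sorted library of the same number was the highest in 14 of 14 cases of gene and fraction, 100%, where chance gives 33.3%. The cases are not independent, since 6 of the 7 genes came from replicate 1, and Magi1 lay at 1.32 CPM in B220 LOW replicate 3 against 1.24 in replicate 1. Across genes, 6 of 6 sorted libraries also deviated most like the iMLL-ENL total library of their number. Of 9 pairs of a wt LSK and a same-numbered leukemic library, 2 correlated above 0.1, both of number 2. They were wt LSK with iMLL-ENL total (0.160) and with B220 HIGH (0.116), against -0.0102 with B220 LOW. Handling shared by number in all 4 groups is argued against for numbers 1 and 3, where the highest such correlation was 0.0164. It stays open for number 2, where Siglech was also high in wt LSK (74.7 CPM) and in B220 HIGH (66.7 CPM). Handling shared among leukemic libraries alone stays open too.

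Cells other than leukemic cells in the B220 HIGH gate could account for the genes higher there, whose summed level with the block was 12479, 20112 and 37692 CPM in B220 HIGH replicates 1, 2 and 3 and 4267, 4892 and 7712 CPM in B220 LOW. Normal B cells are argued against, as in 0 of 3 pairs were Cd79a, Cd79b and Ms4a1 together higher in B220 HIGH by over 10 CPM (8.61, 14 and 9.61 against 7.07, 14.7 and 6.13 CPM), though a small share in replicate 2 stays open, where Ebf1 was 14.1 CPM in B220 HIGH and 0.223 CPM in B220 LOW. Plasmacytoid dendritic cells, which carry B220, are argued against in replicates 1 and 3, where Siglech reached 2.02 CPM, and stay open in replicate 2, where it was 66.7 CPM and no value decides. Macrophages that express C1q are argued against as the source of the whole rise, since C1qa, C1qb and C1qc together had 4.21, 6.78 and 1.11 CPM in B220 HIGH replicates 1, 2 and 3, lowest where the rise was largest, but with 0 counts in B220 LOW a small share stays open, as do monocytes or macrophages with little C1q. Eosinophils, basophils or mast cells and conventional dendritic cells were not tested here and stay open. Cpa3 had 819, 52.5 and 876 CPM in B220 HIGH replicates 1, 2 and 3 and at most 11.4 CPM in B220 LOW. Cd74 had 117, 1783 and 123 CPM in B220 HIGH replicates 1, 2 and 3 and at most 15.5 CPM in B220 LOW. A difference of the leukemic cells themselves, the design's own contrast, stays open and untested.

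The mature neutrophil genes higher in iMLL-ENL total could come from normal marrow cells mixed with leukemic cells. A share of ungated marrow would also bring erythroid cells, and 11 of 13 erythroid genes tested were lower in iMLL-ENL total than in wt LSK. That direction cannot decide the question, since wt LSK itself expressed such genes (Car2 at 570 ± 35.6 CPM), which can hide a small share. Hba-a1, Hbb-bt and Ahsp were also missing from the tables. Car2 stood at 0.369 ± 0.339 CPM in iMLL-ENL total, and levels in normal marrow were not measured here. The depletion of mature lineages from wt LSK keeps mature neutrophil genes low there by design. Beside it, a share of ungated marrow, normal neutrophils alone, a gate not given in the labels, and maturation of the leukemic cells stay open.

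Splits of 6 libraries into 3 and 3 number 10, and 4 when all pairs are parted, too few for a share under 0.05. Every other split puts libraries of both groups on each side, so a difference between the groups adds to the spread and lowers the gene calls. Counts of 0 genes in the other splits are therefore no measure of chance. For iMLL-ENL total against wt LSK, 1 of 10 splits, the real one, gave as many changed genes (4221, against 0 as the highest other), and 7 of 10 gave as many shifted lists (10, against 8 to 14 in the others). For B220 HIGH against B220 LOW, 10 of 10 gave as many changed genes (0, against 0) and 1 of 10 as many lists (15, against 10). With the block, 1 of 4 gave as many genes (79, against 0) and 1 of 4 as many lists (13, against 11).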
